A study of Mus musculus with 21 samples.

How the data were processed

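The series holds chromatin, RNA and bisulfite libraries of mouse sperm and round spermatids, 21 samples in all. The data analysed here come from 1 of them, a bisulfite library of the nucleosome-associated DNA of C57BL/6 sperm; the other 20 samples were not analysed here. Per the labels' protocols, sperm were collected by swim-up, which selects motile cells, and mononucleosomal chromatin was prepared with micrococcal nuclease (MNase), an enzyme that digests the DNA between nucleosomes and leaves the wrapped DNA. Bisulfite treatment converts unmethylated cytosine to uracil, which is read as thymine, whereas methylated cytosine is still read as cytosine.

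Per the file headers, the deposited table gives for each CpG its chromosome, its position, the count of all reads and the count of methylated reads. Both are raw counts with no normalization by the authors that the table shows. Per the submitters' processing notes, Bowtie and the mm9 genome build were used. The trimming, the bisulfite alignment settings, the treatment of duplicate and multiply placed reads and the conversion rate are not given in the sources used here. Tested on the file, the smallest number of reads of a listed CpG was 1, so CpGs without reads are not listed. No listed positions were closer than 2 bp, so each CpG has 1 entry. Whether that entry combines the reads of both strands was not tested. No entry had more methylated than total reads. The last listed position on chromosome 1 was 197195360. Coordinates are given as in the table, on mm9. The table does not state whether its positions count from 0 or 1, so each may be shifted by 1 bp. The mm9 sequence and a gene annotation on mm9 were not used here, so neither genes nor exons are assigned to positions; the planned promoter comparison of 9 gene lists was not run.

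The table lists 15544856 CpGs with 60995624 CpG reads, where a read that covers several CpGs counts at each of them. The median depth was 3 reads per listed CpG, 24.5% of the CpGs had 1 read, 23.1% had 5 or more and 1.96% had 10 or more. PCR reads without molecular identifiers are not independent molecules, and a read counts at each CpG it covers. Binomial intervals treat all CpG reads as independent, so they are too narrow and cover counting error at most. Because there is 1 library, no test between groups was possible and no p-value is given.

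The methylation level is the number of methylated reads over all reads, in percent. For single CpGs a minimum of 10 reads was set. CpG density is the number of listed CpGs within 100 bp on each side of a CpG, itself included, in classes of 1 or 2, 3 to 5, 6 to 9, 10 to 14, and 15 or more. CpGs without reads are not listed, so this density is a lower bound. Methylation state is the pooled level of the CpGs within 100 bp (at least 10 reads), called low under 20%, high over 80% and intermediate otherwise. Coverage was averaged over listed CpGs without those above the 99.9th percentile, which was 19 reads. Regions of low methylation were runs of at least 4 CpGs with at least 5 reads each, with a running level over 3 CpGs under 50% and gaps of at most 500 bp, divided at 30 CpGs. The CpGs of 5 reads or more that define a region are a selected part of its listed CpGs, so coverage of regions was taken over all listed CpGs inside them. Intervals of genome-wide values are 95% percentile intervals from 1000 bootstrap draws of 10 Mb blocks, and intervals of single regions are 95% Wilson binomial intervals. Both describe this library and not the variation between animals. The number of CpGs without reads was estimated with a negative binomial distribution truncated at 0 and above 19 reads.

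Regions are named by a rule fixed before the data were examined, as were the density classes, the state thresholds and the other settings tried, except the truncated distributions, the density of regions over all their listed CpGs and the pooling of all listed CpGs. The rule takes the 5 autosomal regions of 30 or more CpGs with the highest mean coverage, the 5 longest such regions, and the 5 best covered stretches of at least 15 consecutive CpGs within 1000 bp, all over 80% methylated with at least 10 reads each. Alternatives were other read minimums (5 and 20), autosomes only, pooled reads, density over 250 bp on each side, other limits on high coverage, stricter state thresholds, a state taken only from CpGs beyond 100 and up to 1000 bp away, medians, and other region settings. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures by matplotlib 3.10.9. They were tested on simulated reads at the CpG positions of chromosome 19 (420441 simulated CpGs), where a true coverage ratio of 1.5 was recovered as 1.51 by the truncated distribution. With no simulated effect and the state from flanking CpGs, the coverage ratio of low over high at 10 to 14 CpGs came out as 0.985. The simulation drew reads independently at each CpG from a negative binomial distribution, the same kind that was fitted. The recovery of 1.51 thus does not test how well that distribution describes the real reads. In it 3.86% of the sparse CpGs had no reads, so larger shares without reads were not tested. The simulation also did not test the state from CpGs within 100 bp, nor the ratio of low over high at 15 or more CpGs. Of the CpGs placed in CpG-rich regions in the simulation, 98.1% were truly unmethylated.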

Results

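Methylation of CpGs was measured in the DNA that remained wrapped in nucleosomes in mouse sperm, cells in which most histones are replaced by protamines. The series concerns histones, their variants and their marks in sperm and in the spermatids that precede them, and its title relates nucleosome retention to how dense and how methylated CpGs are. The bisulfite library bears on this with 2 measurements at each CpG, the methylation level of the recovered DNA and the number of reads that cover it. It held 60995624 CpG reads over 15544856 CpGs, with a median of 3 reads per listed CpG. There was 1 library of this kind and hence no biological replicate, so the intervals below describe the spread along the genome within it.

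The first question was how far nucleosome-associated sperm DNA is methylated. Most CpGs were either nearly unmethylated or nearly fully methylated. Of the 304889 CpGs with 10 or more reads, 46.6% had a level under 20%, 34.0% had a level over 80% and 19.4% lay between. Levels under 10% alone made up 41.7% of these CpGs and levels of 90% or more 30.4%. Their mean level was 44.2% (95% interval 43.3 to 45.1).

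That mean describes well covered CpGs and not the library as a whole. Pooled over all listed CpGs of up to 19 reads, 73.9% of the CpG reads were methylated (73.3 to 74.4), and CpGs with 5 or more reads had a mean level of 69.3% (68.7 to 69.9). The level fell steadily with the depth of the CpG. It was 83% at CpGs with 1 read (82.7 to 83.3), 74.3% at those with 5 or 6 reads (73.7 to 74.8), 46.6% at those with 10 to 14 reads (45.7 to 47.6) and 22.6% at those with 15 to 19 reads (21.3 to 24.0). CpGs in the densest surroundings made up 1.93% of the CpGs with 1 read and 56.4% of those with 15 to 19 reads. At a single CpG of median depth the level is too coarse to be read. What follows therefore rests mainly on CpGs with 10 or more reads and on reads pooled over several CpGs.

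**Figure D1:**
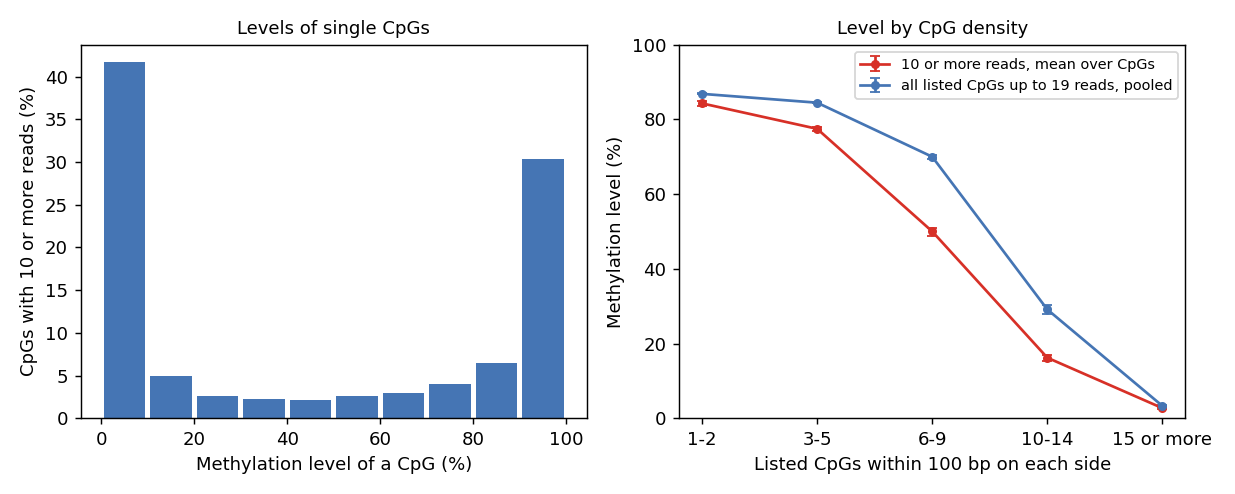
Left, share of the CpGs with 10 or more reads (percent) by methylation level in steps of 10%. Right, methylation level (percent) by the number of listed CpGs within 100 bp on each side, for CpGs with 10 or more reads (mean over CpGs) and for all listed CpGs up to 19 reads (pooled reads), with 95% block bootstrap intervals; both curves fall, from 84.3% and 86.8% at 1 or 2 CpGs to 2.71% and 3.3% at 15 or more.

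The second question was how methylation depends on CpG density. Methylation fell with every step in density. Among CpGs with 10 or more reads the mean level was 84.3% at 1 or 2 listed CpGs within 100 bp on each side, itself included (83.7 to 84.8), 77.5% at 3 to 5 (76.9 to 78.0), 49.99% at 6 to 9 (48.9 to 51), 16.2% at 10 to 14 (15.3 to 17.0) and 2.71% at 15 or more (2.53 to 2.93). In the densest class 97.4% of these CpGs had a level under 20% and 0.164% had a level over 80%. Pooled over all listed CpGs of up to 19 reads, the levels were 70.0% at 6 to 9 CpGs and 29.1% at 10 to 14, against 86.8% and 3.3% in the sparsest and densest classes.

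The third question was whether the DNA recovered in nucleosomes differs in amount with CpG density and methylation, for which coverage is the measure in this library. Mean coverage of listed CpGs was higher in each denser class. The mean was 2.78 reads per listed CpG at 1 or 2 CpGs (2.75 to 2.80), 3.23 at 3 to 5 (3.22 to 3.25), 3.65 at 6 to 9 (3.63 to 3.67), 4.25 at 10 to 14 (4.21 to 4.30) and 5.34 at 15 or more (5.30 to 5.38). The densest class held 5.40% of the listed CpGs of up to 19 reads and 8.89% of the reads on such CpGs. Since CpGs without reads are not listed, these means lie above the true ones, more so in the sparse classes. Deeply covered DNA also has more of its CpGs listed and so falls into denser classes, so part of the rise is built into the counting of density, and the size of that part was not measured. The truncated negative binomial distribution put the means at 2.15 and 5.16 reads in the sparsest and densest classes, with an estimated 22.6% and 4.12% of CpGs without reads.

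Within each class of 3 or more CpGs, mean coverage was higher in unmethylated than in methylated surroundings, and the gap was wider in the denser classes. Density was not matched between the states inside a class, and the class of 15 or more has no upper limit. How far this contributes to the gap was not tested. At 15 or more CpGs the mean was 5.36 reads in the low state (5.33 to 5.40, 813613 CpGs) and 3.45 in the high state (3.31 to 3.60, 7233 CpGs), a ratio of 1.55 (1.49 to 1.63). CpGs of intermediate state in this class lay between, at 4.82 reads (4.65 to 5.0, 17562 CpGs). The ratio of low over high was 1.30 at 10 to 14 CpGs (1.28 to 1.32), 1.17 at 6 to 9 (1.16 to 1.18) and 1.05 at 3 to 5 (1.04 to 1.05). At 1 or 2 CpGs it was 1.05 (1.04 to 1.07), with 0.899 at a minimum of 20 reads (0.852 to 0.946). It did not differ from 1 beyond its interval with a minimum of 5 reads, at 0.994 (0.985 to 1.004), or without CpGs above the 99th percentile of coverage, at 0.992 (0.981 to 1.005). It was 1.06 with the state from flanking CpGs only (1.05 to 1.08) and 1.06 with density counted over 250 bp on each side (1.04 to 1.09), and 1.58 with no limit on coverage (1.25 to 2.0). The direction in this class thus changed with the setting.

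Coverage cannot be compared across density classes when the state is taken from the CpG's own surroundings, since a minimum of 10 reads over 1 or 2 CpGs admits only deeply covered ones. Measured in that way, the densest class had 0.805 of the coverage of the sparsest in the low state (0.79 to 0.818) and 0.545 in the high state (0.521 to 0.568). With the state taken only from CpGs beyond 100 and up to 1000 bp away, both ratios turned round; a minimum of 5 reads turned the ratio of the low state alone, to 1.24 (1.23 to 1.25), and left the high state at 0.792 (0.758 to 0.826). Coverage in the low state then rose from 3.03 reads at 1 or 2 CpGs (2.99 to 3.06) to 5.38 at 15 or more (5.34 to 5.42), a ratio of 1.78 (1.76 to 1.80). In the high state it rose from 2.84 (2.83 to 2.86) to 3.55 (3.42 to 3.69), a ratio of 1.25 (1.20 to 1.30). The rise with density in the low state was 1.42 times that in the high state (1.37 to 1.48). The ratio of low over high at 15 or more CpGs was 1.51 with this definition (1.45 to 1.57).

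**Figure D2:**
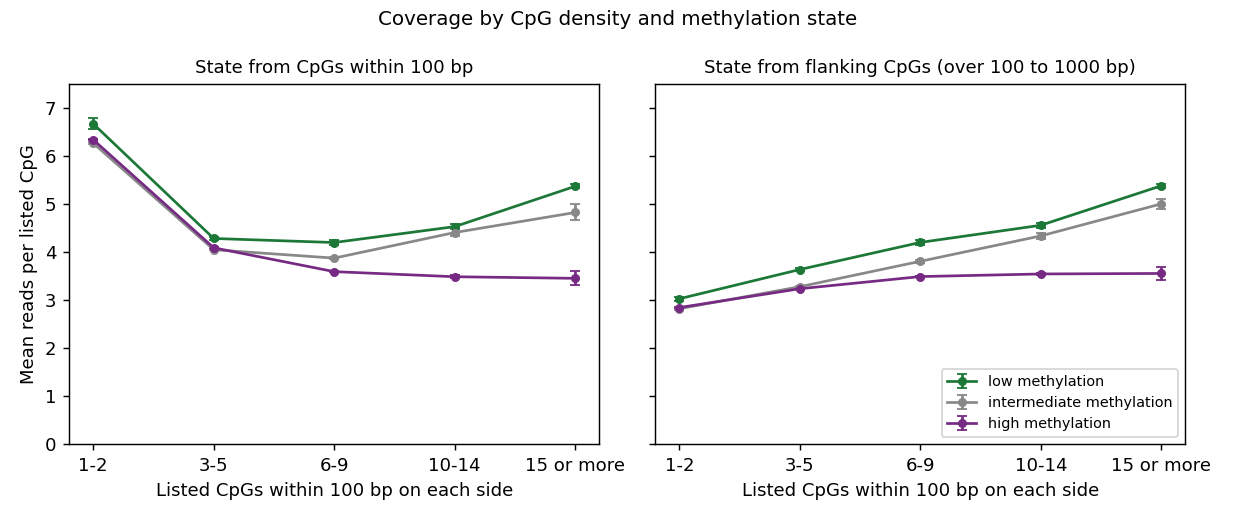
Mean reads per listed CpG by the number of listed CpGs within 100 bp on each side, for CpGs in surroundings of low (under 20%), intermediate and high (over 80%) methylation, with 95% block bootstrap intervals; the state comes from CpGs within 100 bp (left) or only from CpGs beyond that and up to 1000 bp away (right). At 15 or more CpGs the low state lies at 5.36 and 5.38 reads and the high state at 3.45 and 3.55.

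Stretches of unmethylated DNA were then located along the genome. There were 9308 CpG-rich regions of low methylation with 30 or more CpGs and 20175 shorter ones. The CpG-rich regions had a median length of 1519 bp and a median level of 2.84% (quartiles 1.81% and 4.48%), and covered 15.8 Mb. The shorter regions had a median length of 464 bp and a median level of 17.9% (quartiles 5% and 30.05%). CpG-rich regions held 6.44% of the listed CpGs of up to 19 reads and 10.97% of the reads on such CpGs. Their mean was 5.52 reads per listed CpG (5.49 to 5.55) and their pooled level was 3.71% (3.61 to 3.81). The shorter regions had a mean of 4.74 reads (4.70 to 4.78) and a pooled level of 13.7% (13.2 to 14.2), and the rest of the genome 3.03 reads (3.01 to 3.05) and 85.9% (85.8 to 86.1).

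Coverage in the CpG-rich regions was thus 1.82 times that of the rest (1.81 to 1.84), and in the shorter regions 1.56 times (1.55 to 1.58). Because regions were called from CpGs with 5 or more reads, part of this excess comes with the selection, and with a minimum of 10 reads per CpG 786 CpG-rich regions were called and the ratio was 2.5, with 2.35 for the shorter regions. The rest of the genome supplied 84.8% of the CpG reads on CpGs of up to 19 reads. CpGs above 19 reads held 17.5% of all CpG reads and are left out of this share.

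Around the middle of the autosomal CpG-rich regions the 2 measurements moved in opposite directions. Within 300 bp of the middle, coverage averaged 5.68 reads per listed CpG and the level was 2.52%. Between 4000 and 5000 bp from the middle, coverage averaged 3.54 reads and the level was 60.6%. The regions were called for low methylation from CpGs with 5 or more reads. Part of both differences thus comes with the selection, and its size was not measured. The level at 4000 to 5000 bp was also still below the 85.9% of the rest of the genome.

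**Figure D3:**
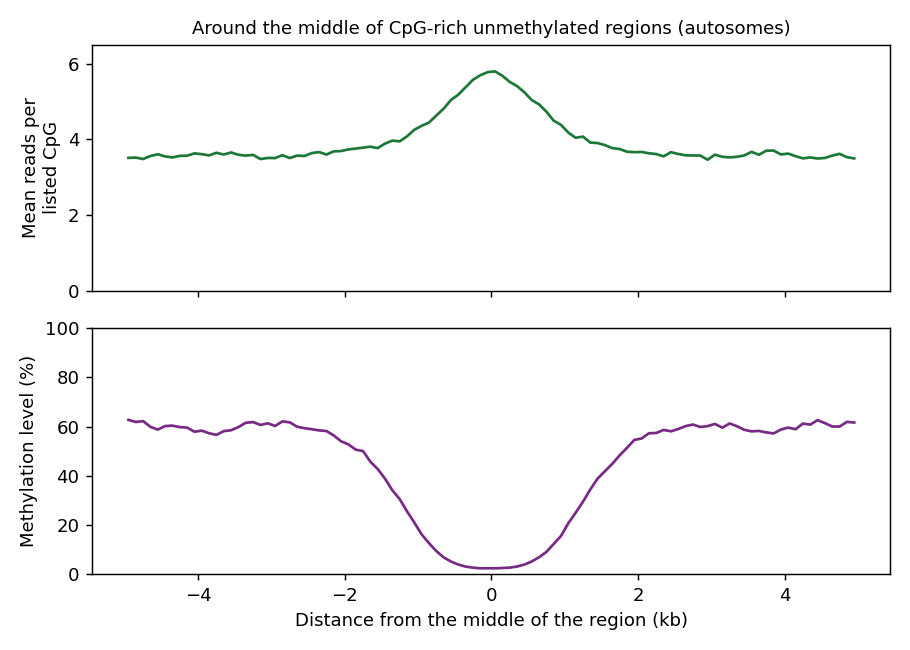
Mean reads per listed CpG (top) and pooled methylation level in percent (bottom) in 100 bp bins by the distance in kb from the middle of autosomal CpG-rich unmethylated regions. Coverage averages 5.68 reads within 300 bp of the middle and 3.54 reads beyond 4000 bp, whereas the level averages 2.52% and 60.6%. The regions were called for low methylation from CpGs with 5 or more reads, so part of both differences comes with the selection.

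Over 9261 autosomal regions with at least 30 CpGs of up to 19 reads the median was 5.47 reads per listed CpG, with the central 90% of regions between 4.07 and 7.63. Across these regions, which are not independent replicates, coverage had a Spearman correlation of -0.0616 with the number of listed CpGs per 100 bp (-0.0827 to -0.0418) and -0.138 with length. Counting only CpGs of up to 19 reads, which makes deeply covered regions look sparser, the former was -0.0695 (-0.0903 to -0.0496). A region needs at least 30 CpGs of 5 or more reads, so short or sparse regions enter only if well covered. That selection can by itself make both correlations negative, and its size was not measured. With the regions divided into 4 groups by listed CpGs per 100 bp, the mean was 5.79 ± 1.21 (SD, 2316 regions) in the sparsest group and 5.57 ± 1.09 (SD, 2315 regions) in the densest.

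The autosomal CpG-rich regions were ranked by mean coverage without CpGs above 19 reads, and the order differs when these are counted. The highest such mean was found on chromosome 14 from 66349363 to 66349978, with 13.1 ± 3.66 reads per listed CpG (SD over 36 CpGs) and a level of 14.5% (Wilson interval 11.7 to 17.9, from the CpGs with 5 or more reads, as for all regions named here). A region on chromosome 1 from 90173251 to 90174957 followed, with 12.4 ± 4.47 reads over the 35 CpGs of up to 19 reads among the listed ones, and a level of 7.99% (6.72 to 9.47). This region had 73 CpGs with 5 or more reads, so most of those lay above 19 reads and are left out of its mean. The region on chromosome 7 from 20394048 to 20395453 had 11.6 ± 4.71 reads (38 CpGs) and a level of 19.4% (16.7 to 22.4). The region on chromosome 14 from 45478175 to 45479307 had 11.1 ± 3.44 reads (48 CpGs) and a level of 4.24% (2.89 to 6.19). The region on chromosome 17 from 37333770 to 37334663 had 11.1 ± 4.08 reads (75 CpGs) and a level of 1.45% (0.85 to 2.46).

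The 5 longest CpG-rich regions had means between 5.21 and 6.09 reads. The longest spanned 14619 bp on chromosome 4 from 109646626 to 109661244, with 5.89 ± 3.25 reads per listed CpG (SD over 657 CpGs) and a level of 3.29% (2.73 to 3.95). The next were 10534 bp on chromosome 12 from 57789297 to 57799830 (5.98 ± 3.09 reads over 369 CpGs, level 4.28%, 3.43 to 5.31) and 10123 bp on chromosome 16 from 91219700 to 91229822 (6.09 ± 3.35 reads over 438 CpGs, level 3.25%, 2.59 to 4.07). A region of 9698 bp on chromosome 9 from 62990123 to 62999820 had 5.92 ± 3.55 reads over 552 CpGs and a level of 3.32% (2.71 to 4.08). A region of 8667 bp on chromosome 5 from 38212252 to 38220918 had 5.21 ± 2.96 reads over 379 CpGs and a level of 5.05% (4.06 to 6.27).

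A single stretch of at least 15 consecutive CpGs within 1000 bp had 10 or more reads and a level over 80% at every CpG. It lay on chromosome 13 from 120281582 to 120282652, with 21 CpGs, a mean of 27.3 reads per CpG and a level of 95.8% (Wilson interval 93.9 to 97.2). As a whole, these 21 CpGs extend slightly beyond the 1000 bp of the rule. Without CpGs above 19 reads there was no such stretch on the autosomes. At this depth such stretches are hardly detectable, since 1.96% of the listed CpGs reached 10 reads.

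Coverage of CpGs near each other was correlated, and the decay with distance differed between unmethylated regions and the rest. In the CpG-rich regions of the autosomes the correlation fell to 0.139 at 41 to 60 bp (0.131 to 0.148), rose again to 0.213 at 81 to 100 bp (0.205 to 0.222) and was 0.003 above 200 and up to 220 bp (-0.005 to 0.011), with a lower second rise to 0.051 at 261 to 280 bp (0.044 to 0.057). In the rest of the autosomes the correlation fell from 0.218 at 41 to 60 bp (0.214 to 0.222) to 0.127 at 81 to 100 bp (0.124 to 0.13). The difference between 81 to 100 bp and 41 to 60 bp was 0.074 in CpG-rich regions (0.067 to 0.082), -0.090 in the rest (-0.093 to -0.088) and 0.00014 in the shorter regions (-0.0094 to 0.00937).

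**Figure D4:**
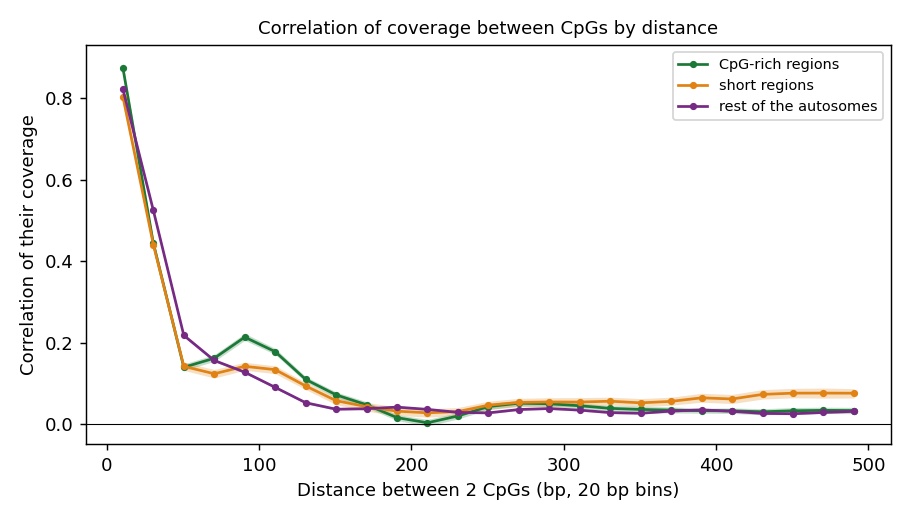
Correlation of the coverage of 2 CpGs by their distance in 20 bp bins, on autosomes, for CpG-rich regions, shorter regions of low methylation and the rest, with 95% block bootstrap intervals as bands. In CpG-rich regions the correlation is 0.139 at 41 to 60 bp and 0.213 at 81 to 100 bp, whereas in the rest it is 0.218 and 0.127.

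The 19 autosomes resembled one another, and the sex and mitochondrial chromosomes stood apart in coverage. Mean coverage of listed CpGs was 3.27 ± 0.05 reads (SD over 19 autosomes, range 3.2 on chromosome 3 to 3.35 on chromosome 11) and 2.06 on the X chromosome, below every autosome. The ratio of X over autosomes was 0.629 (0.619 to 0.64), and 0.436 between means that include the estimated CpGs without reads. The latter rests on the fitted distribution and may be too low. Autosomal reads thinned to this share were shallower than X in each density class, with 2.17 against 2.49 reads per listed CpG at 6 to 9 CpGs. A sperm carries X or Y, so X is present at a lower dose than the autosomes. The lower coverage of X is therefore by itself no measure of nucleosome retention. The Y chromosome had 5980 listed CpGs, of which 5.45% were above 19 reads and the others averaged 2.37 reads.

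The pooled level was 74.0% ± 1.81 (SD over 19 autosomes, range 70.0% on chromosome 11 to 76.2% on chromosome 1), 73.5% on X and 70.5% on Y. Among CpGs with 10 or more reads, the mean level was 44.2% on autosomes (43.2 to 45.1) and 47.1% on X (37.5 to 55.0, 1451 CpGs), a comparison that mixes densities and whose intervals overlap. Over all listed CpGs of up to 19 reads with 6 to 9 CpGs within 100 bp on each side, the pooled level was 49.5% on X (46.5 to 52.9) and 70.2% on autosomes (69.5 to 70.8); X was lower with separate intervals in 4 of the 5 density classes. Density is counted lower on X, where an estimated 41% of CpGs had no reads, against 14.9% on autosomes. The 41% rests on the same fitted distribution and may be too high. Autosomal reads thinned past the depth of X gave 17.6% at 10 to 14 CpGs (16.8 to 18.5), within the interval of X. At 1 or 2, 3 to 5 and 6 to 9 CpGs the thinned autosomal level stayed above X. The mitochondrial chromosome had 116 listed CpGs with 234 reads in all, of which 19 were methylated, a level of 8.12% (Wilson interval 5.26 to 12.3).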

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

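No paired analysis was possible because the analysed data come from 1 library. The alternatives by truncated distributions, by counting the density of regions over all their listed CpGs and by pooling all listed CpGs of up to 19 reads were chosen after seeing the data; the others were chosen before. The planned comparison of promoters, with its wider promoters and higher read minimum, was not run, since no annotation on mm9 was used. Of 118 alternative values, 43 stayed within the interval of the main value (for numbers of regions, within 1.5 times), 69 moved beyond it and 6 reversed. Depth limits levels of single CpGs, since 1.96% of listed CpGs have 10 or more reads. The mean level of 44.2% became 69.3% at a minimum of 5 reads, 25.5% at 20 reads, 48.9% with pooled reads and 73.9% over all listed CpGs of up to 19 reads. A higher minimum leaves a more CpG-dense, less methylated set. At 1 or 2 CpGs the level of 84.3% became 86.6% and 60.5% (minimum 5 and 20), 85.96% (250 bp on each side) and 86.8% (all listed). At 15 or more CpGs, 2.71% became 3.15%, 3.72%, 2.27% and 3.3%. All levels at a minimum of 20 come from the 13008 CpGs above 19 reads, which the coverage means leave out. At 1 or 2 CpGs a change of density class cannot account for the fall to 60.5%. The ratio of coverage, low over high, at 15 or more CpGs (1.55) ranged over 1.46 (250 bp), 1.43 (without the top 1% of coverage), 1.67 (medians) and 1.68 (truncated distribution). At 3 to 5 CpGs (1.05) it was 1.04 (minimum 20), 1.04 (250 bp), 1.07 (no limit on coverage), 1.01 (without the top 1%), 1.12 (flanking state), 1.04 (stricter states), 1 (medians) and 1.02 (truncated distribution). At 1 or 2 CpGs it fell below 1, to 0.899 at a minimum of 20 (0.852 to 0.946), and to 0.994 (minimum 5) and 0.992 (without the top 1%), whose intervals include 1; the cause was not tested. The ratio of the densest over the sparsest class in the low state (0.80) was 1.24 (minimum 5), 0.54 (minimum 20), 0.97 (250 bp), 0.57 (no limit), 1.78 (flanking state), 0.83 (medians) and 0.78 (truncated distribution). In the high state (0.54) it was 0.79, 0.32, 0.70, 0.59, 1.25, 0.50 and 0.49. A read minimum over few CpGs admits only deeply covered ones, which the flanking state avoids. With at least 10 reads per CpG the regions fell to 786 CpG-rich and 10174 shorter ones, since fewer CpGs qualify, and coverage over the rest rose from 1.82 to 2.5; dividing at 20 CpGs gave 1.79. The coverage of X over autosomes (0.63) was 0.67 with medians and 0.44 with truncated distributions, which may be too low. Of the other results, 28 values moved, 20 did not and 3 reversed, those at 1 or 2 CpGs above.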

Other observations

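The tests with the flanking state and across density classes for conversion, amplification or mapping were written after their results were seen, the truncated distribution was added after seeing the data, and the stretches, windows and sites named here were chosen after their values were seen. Not all CpG-dense DNA of the library was unmethylated. In the densest class, 97.0% of the CpGs were in the low state, 2.09% in the intermediate and 0.86% in the high state. There were 156 stretches of 15 or more consecutive CpGs of this class in the high state and 374 in the intermediate state. The reads given for a stretch are CpG reads, so the same read can count at several CpGs and the Wilson intervals are too narrow. The 5 stretches in the high state with the most CpGs were one on chromosome 10 from 80606772 to 80607172 (41 CpGs, 91.6% of 215 reads methylated, Wilson interval 87.2 to 94.6), one on chromosome 9 from 121037068 to 121037428 (39 CpGs, 98.9% of 93 reads, 94.2 to 99.8), one on chromosome 11 from 109149978 to 109150188 (36 CpGs, 87.8% of 82 reads, 79.0 to 93.2), one on chromosome 3 from 126808970 to 126809150 (29 CpGs, 99.2% of 131 reads, 95.8 to 99.87) and one on chromosome 19 from 24205464 to 24205740 (28 CpGs, 83.6% of 140 reads, 76.6 to 88.8). The stretch of intermediate state with the most CpGs lay on chromosome 10 from 79439497 to 79440268 (71 CpGs, 52.8% of 284 reads, 47.0 to 58.5). The next lay on chromosome 12 from 72419107 to 72419692 (59 CpGs, 28.4% of 317 reads, 23.7 to 33.6) and on chromosome 8 from 72975612 to 72976224 (55 CpGs, 42.0% of 381 reads, 37.1 to 47.0). They were followed by stretches of 50 CpGs on chromosome 12 from 112215169 to 112215652 (30.2% of 301 reads, 25.3 to 35.6) and on chromosome 17 from 26568764 to 26569207 (43.2% of 234 reads, 37.0 to 49.6).

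The higher coverage of unmethylated CpG-dense DNA is the pattern closest to the title of the series. The tables argue against the reads of a CpG deciding its own state as the whole cause, since the ratio was 1.51 (1.45 to 1.57) with the state from flanking CpGs. They also argue against collapsed repeats covered by more than 11 reads as the whole cause. Without the top 1% of coverage, which lies above 11 reads, the ratio was 1.43 (1.37 to 1.49). Collapsed repeats of lower coverage stay in this comparison, so it cannot test them. The missing CpGs without reads are argued against too, since estimating them gave 1.68 (1.66 to 1.72 over leaving out each autosome). Of the causes weighed, bisulfite conversion, amplification or mapping that differs with methylation stays open, as do collapsed repeats of lower coverage. Other technical causes were not examined, nor was a difference of density between the states inside a class. The ratio with the state from flanking CpGs was 1.12 at 3 to 5 CpGs (1.12 to 1.13) against 1.51 at 15 or more. The gap thus grew with the number of CpGs, as a bias that differs with methylation also could, and no unconverted library was analysed. Greater retention of nucleosomes on unmethylated CpG-dense DNA may be the biological explanation, and no comparison between groups tested it.

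The first rise in the correlation of coverage, at 81 to 100 bp in CpG-rich regions, might come from fragments with fixed ends, as positioned mononucleosomes would give. The shorter regions, tested for the same rise, gave a difference of 0.00014 (-0.009 to 0.009), so the predicted rise over 41 to 60 bp was not seen there. Their correlation was nevertheless lower between these distances, at 0.123 at 61 to 80 bp (0.113 to 0.134), than at 81 to 100 bp, where it was 0.142 (0.132 to 0.152). These intervals overlap slightly, and none was computed for the difference. A rise as large as in CpG-rich regions (0.074) lies outside this interval, whereas a small one does not; that an interval spanning 0 leaves the explanation open was decided after the value was seen. Above 200 bp the correlation of the shorter regions climbed on the whole, to 0.053 at 261 to 280 bp and 0.076 at 461 to 480 bp. That of the CpG-rich regions fell from 0.051 to 0.033 between these distances. The difference at 261 to 280 bp, against above 200 and up to 220 bp, was 0.026 (0.015 to 0.037) in the shorter regions. It is part of their climb and no separate peak. The same difference was 0.048 (0.040 to 0.055) in CpG-rich regions and -0.0004 (-0.003 to 0.002) in the rest. These distances were chosen from the curve of the CpG-rich regions, and the rest had a rise of its own elsewhere, from 0.0272 at 241 to 260 bp (0.0248 to 0.0298) to 0.0379 at 281 to 300 bp (0.0356 to 0.0406), after a smaller one with overlapping intervals from 0.0362 at 141 to 160 bp (0.0336 to 0.0391) to 0.0414 at 181 to 200 bp (0.0384 to 0.0444). Fragment lengths and read lengths, which would set these distances, were not used here.

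The X chromosome was less methylated than the autosomes in every density class but the densest. At 1 or 2 CpGs the pooled level was 85.2% on X (84.2 to 86.0) and 86.9% on autosomes (86.7 to 87.0). At 3 to 5 CpGs it was 79.9% on X (79.0 to 80.7) and 84.5% on autosomes (84.3 to 84.7), whereas at 15 or more it was 5.88% (3.41 to 10.7) and 3.27% (3.15 to 3.41). At 6 to 9 CpGs the pooled level was 49.5% on X (46.5 to 52.9) and 70.2% on autosomes (69.5 to 70.8), and at 10 to 14 CpGs it was 15.7% (13.2 to 19.2) and 29.3% (28.2 to 30.5). A candidate explanation is that fewer CpGs are listed on X, which lowers the counted density. When autosomal reads were thinned to 0.44 of their number and densities counted again, the autosomal level at 6 to 9 CpGs was 62.5% (61.6 to 63.4), still above X, so this explanation accounts for at most part of the gap. At 10 to 14 CpGs the thinned level was 17.6% (16.8 to 18.5), within the interval of X. Thinned autosomes were shallower than X, with 2.17 against 2.49 reads per listed CpG at 6 to 9 CpGs and 2.42 against 2.89 at 10 to 14, so they were thinned past the depth of X and the match at 10 to 14 CpGs is not one at equal depth. At 3 to 5 CpGs the thinned level was 83% (82.8 to 83.3), above X. A difference of the chromosomes themselves was not tested.

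CpGs above 19 reads, 13008 of them, held 17.5% of all reads at a pooled level of 50.7%, and 95.3% of these reads lay in 20 windows of 10 kb, with 87.0% in stretches of such CpGs over 300 bp long. The window on chromosome 2 from 98500001 to 98510000 alone held 13.5% of all CpG reads of the library. In that window the CpG at 98502984 was counted as methylated in 190 of 296980 reads (0.064%). The next listed CpGs with over 2000 reads, 23 bp before and 29 bp after it, had levels of 61.3% and 58.1%. Bisulfite reads do not tell an unmethylated cytosine from a thymine in the DNA itself, so the count at 98502984 need not reflect methylation. The CpG-rich region on chromosome 17 from 39979946 to 39985767 had a mean of 375 reads per listed CpG and a level of 11.1%.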
